A study of Mus musculus with 32 samples.

How the data were processed

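Brains came from 4 mice of each of 2 lines of C57BL/6 background, Cx3cr1-CreER and Sall1-CreER, both with the RPL22-HA (RiboTag) allele. All mice received 5 mg of tamoxifen by gavage on 4 occasions every other day at 4 to 6 weeks of age. Microglia were isolated by enzymatic digestion, a Percoll gradient and flow cytometry, whereas direct precipitation started from whole brain homogenate in a buffer with cycloheximide. The anti-HA antibody or a mouse IgG1 control was used, and polyadenylated RNA was sequenced.

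The deposited table holds raw read counts over exons for 24411 genes in 32 libraries, which the authors had made without normalization. Per the submitters' processing notes, bcl2fastq, HISAT 0.1.5, HOMER and the mouse genome build mm9 were used before the counts were deposited. How multiply mapped reads were treated is not given in the sources used here, nor is the strand setting of the count, so values of genes with near-identical copies and of overlapping genes are uncertain. Coordinates below are those of the deposited table (mm9). Every library's column carries the name given in that sample's description. For the 8 sorted Cx3cr1 libraries, title and antibody label say one thing and description, and hence column name, the opposite. Groups follow the titles, and groups by description are an alternative, as are sums of both sorted libraries of each mouse for comparisons between lines. Gene counts per library ranged from 249881 to 4047465, and no 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 1.75 to 24.8 over 48 pairs). PCR copies were not separated by molecular identifiers, so bounds against a floor of 3 counts cover counting error only. 

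Each comparison was tested with edgeR 4.0.16 (R 4.3.3), with a robust quasi-likelihood fit on the libraries of the compared groups, TMM scaling and the default low-count filter (minimum count 10). Genes with an adjusted p (Benjamini-Hochberg, over all genes tested) under 0.05 were called, and adjusted p values of single genes in the text are from this test. The difference in HA enrichment between lines was an interaction term over the 16 homogenate libraries. The corresponding difference in SortIP over Sort was added after the data had been seen. Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Calls of named lists that held with an estimated correlation were those of microglia, macrophages and disease-associated microglia in Cx3cr1 HA against IgG, microglia in Sall1 HA against SortIP and macrophages in SortIP between lines. In Sall1 HA against Cx3cr1 HA those of microglia, macrophages and astrocytes held, and in the difference in HA enrichment those of microglia, macrophages, MHC class II, astrocytes, oligodendrocytes, their precursors and the respiratory chain. No other list call that the report gives for groups by title held, and for calls by description or from mouse sums this p stands in the text.

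The lists cover homeostatic microglia, perivascular and border macrophages, monocytes, neutrophils, lymphocytes, astrocytes, oligodendrocytes and their precursors, neurons, endothelial, mural and ependymal cells, choroid plexus epithelium, fibroblasts and leptomeninges, immediate early genes, inflammatory cytokines and chemokines, disease-associated microglia, MHC class II, interferon-stimulated genes, nuclear-retained RNAs, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits and mitochondrially encoded mRNAs. Of the last, 0 members have a row in the table used here. Measured members are those that passed the low-count filter. Grouping by title, the lists, the other comparisons and the rule for named genes were fixed before the data were examined. The rule takes Cx3cr1, Sall1 and Rpl22; per comparison and list, the 3 members with the smallest adjusted p in the direction of the list's median and the called member with the smallest adjusted p in the other direction (where none is called, the 2 with the highest mean expression); and per comparison the 5 higher and 5 lower genes with the largest fold change among called genes with a mean log2 CPM of at least 4 and non-overlapping groups. Of 105 called fold changes of single genes named in the report, 104 had all 4 libraries of one group above all 4 of the other. The exception is stated where it is named. Chance gives 2.86% of unchanged genes, either way, but the rule favours called genes and for the largest changes requires non-overlapping groups. The 104 of 105 are thus no support of their own. Genes without a count in any library of a group are given as bounds, since their fitted fold depends on the prior count.

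Samples with the same number within a line came from the same mouse, per the series' design, so the number is a block in an alternative fit. Across the 48 pairs of libraries of a mouse, deviations from the group means correlated with a median r of 0.0972 across genes (from -0.202 to 0.385), and in 30 pairs a library correlated best with that of its own mouse. Other alternatives were DESeq2 1.42.0, median-ratio size factors, total counts without TMM, no low-count filter, all 8 groups in one fit, a fold of at least 2, and leaving out each library. Thinning of all libraries to the shallowest, groups by description together with the replicate block, and adjustment for transcript GC content and length were chosen after seeing the data. The last used a spline per library (5 degrees of freedom) with transcript values matched by symbol for 97.2% of genes from the GENCODE vM21 annotation of another build (GRCm38), of which no coordinate is used. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 33 and 81 in Cx3cr1 HA against IgG (9510 genes), 9 and 55 in the difference in HA enrichment (12005 genes), and 67 and 88 in Sort between lines (8296 genes). At an adjusted p threshold of 0.05, false calls made up 5.79%, 5.88% and 4.32% of calls in these. They were 8.97% in Sall1 HA against SortIP (8737 genes), 8.09% in Sall1 SortIP against Sort (8356 genes), 7.04% in Sall1 HA against Cx3cr1 HA (8164 genes) and 6.21% in Sall1 HA against IgG (11231 genes). In the other 4 comparisons they lay between 3.68% (Cx3cr1 HA against SortIP, 7409 genes) and 5.17% (the difference in SortIP over Sort, 9056 genes). All other simulated genes were unchanged, whereas HA against IgG or SortIP called from 64.5% to 80.2% of the real genes tested. Simulated recovery and false calls therefore need not hold where most genes change. On counts simulated with a GC trend for Sall1 HA against SortIP (8758 genes, 200 of them changed), the adjustment lowered false calls from 2151 to 8. It recovered 162 changed genes, against 165 without it. These genes were drawn at random, so the simulation does not show that real changes tied to GC content or length are kept.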

Results

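Polyadenylated RNA was profiled from the brains of tamoxifen-treated mice of 2 lines, Cx3cr1-CreER and Sall1-CreER, which carry an inducible Cre recombinase. Both lines also carry RiboTag, a conditional allele that adds a haemagglutinin (HA) epitope to the ribosomal protein RPL22 once Cre has acted. Precipitation with an anti-HA antibody recovers RNA bound to tagged ribosomes, so that RNA of recombined cells can be read out of whole tissue. Each of the 4 brains per line was divided into 4 samples, which gives 32 libraries in 8 groups of 4. These were sorted microglia (Sort), sorted microglia followed by anti-HA precipitation (SortIP), anti-HA precipitation directly from brain homogenate (HA), and precipitation of homogenate with an isotype control antibody (IgG). All means below are over n = 4 mice with the SD between mice, and all fold changes are on the log2 scale with their SE. Gene counts per library ranged from 286418 to 574671 in Cx3cr1 HA, from 1894943 to 3027342 in Sall1 HA and from 2200897 to 2470411 in Cx3cr1 IgG. They ranged from 704183 to 4047465 in Sall1 IgG and from 249881 to 1808789 over the 16 sorted libraries. For the 8 sorted Cx3cr1 libraries the titles and the antibody label give one assignment to Sort and SortIP, and the descriptions give the opposite one. They are grouped by title here and called "titled Sort" and "titled SortIP", and for comparisons that use them some values with the described groups are given as well.

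Cx3cr1 encodes the fractalkine receptor of microglia (chromosome 9, 119957801 to 119977414, mm9). Its mean was 864 ± 196 counts per 1e6 gene counts (CPM) in Cx3cr1 HA and 73.1 ± 11.8 CPM in Sall1 HA, against 77.4 ± 14.5 and 59.6 ± 6.30 CPM in the IgG libraries of these lines. Sall1, a transcription factor gene of microglia (chromosome 8, 91551143 to 91568061), reached 130.3 ± 30.9 CPM in Cx3cr1 HA and 30.0 ± 5.02 CPM in Sall1 HA, with 15.1 ± 2.19 and 14.6 ± 6.14 CPM in IgG. In sorted cells the mean of Cx3cr1 was 2612 ± 349.9 CPM (titled Sort) and 3444 ± 1168 CPM (titled SortIP) in the Cx3cr1 line. It was 5419 ± 912 CPM (Sort) and 4378 ± 749 CPM (SortIP) in the Sall1 line. Rpl22, the tagged gene (chromosome 4, 151699835 to 151708191), was at 260.3 ± 11.7 CPM in Cx3cr1 HA and 311 ± 22.4 CPM in Sall1 HA. The 26 homeostatic microglia genes took 10.3 ± 0.432% of all gene counts in Cx3cr1 HA and 0.736 ± 0.0428% in Sall1 HA, against 0.170 ± 0.0205% in Cx3cr1 IgG and 0.133 ± 0.0193% in Sall1 IgG. In the sorted groups they took between 8.63 ± 0.406% (Sall1 Sort) and 10.99 ± 0.481% (Cx3cr1 titled Sort). Astrocyte genes took 2.09 ± 0.154% in Sall1 HA and 0.195 ± 0.0176% in Cx3cr1 HA, against 0.750 ± 0.0466% and 0.765 ± 0.103% in the Sall1 and Cx3cr1 IgG libraries.

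**Figure D1:**
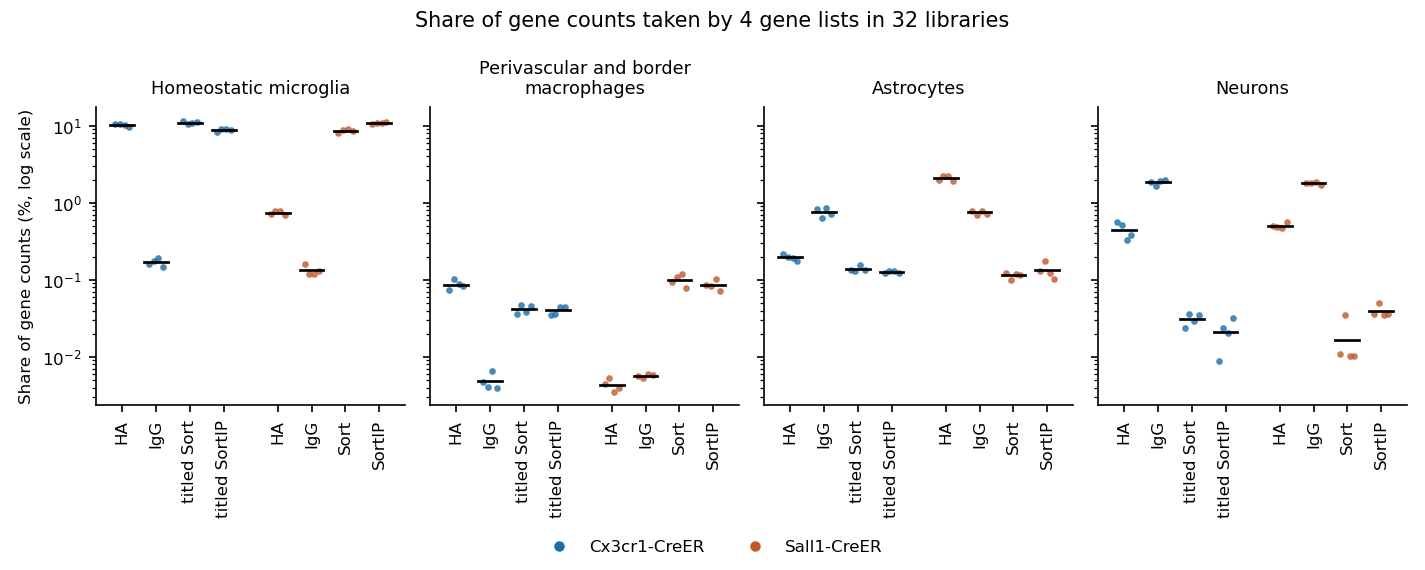
Share of all gene counts taken by 4 gene lists, in percent on a log axis, in each of the 8 groups (sorted Cx3cr1 libraries by title); each point is 1 library and each line the mean of 4. Homeostatic microglia genes averaged 10.3% of counts in Cx3cr1 HA and 0.736% in Sall1 HA, while astrocyte genes averaged 0.195% and 2.09%.

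Cx3cr1 HA was compared with IgG to find the transcripts that the HA antibody recovered above the isotype control when Cre was driven from Cx3cr1. Microglial genes were higher in HA, where 24 of 25 measured members were higher, 0 were lower and 1 did not pass. Their median was 5.35 (camera adjusted p = 7.90e-52, adjusted p = 0.00212 with an estimated correlation), and 25 passed when adjusted over the list alone. C1qa and C1qb, which encode chains of complement component C1q, were higher by 7.18 ± 0.22 and 7.43 ± 0.25. Aif1, the gene of the microglial marker IBA1, was higher by 6.59 ± 0.21 (largest adjusted p of the 3, 4.45e-12). Genes of perivascular and border macrophages rose with them, as all 10 measured members were higher. Their median was 5.23 (camera adjusted p = 4.72e-10, adjusted p = 0.0499 with an estimated correlation), and 10 passed when adjusted over the list alone. Pf4, which encodes platelet factor 4, lay at 6.73 ± 0.35, the scavenger receptor gene Stab1 at 4.53 ± 0.23 and Cbr2 at 5.27 ± 0.33. All 6 measured MHC class II genes were higher, as were 10 of 13 disease-associated microglia genes and 8 of 11 interferon-stimulated genes, with none lower. Adjusted over the list alone, 6, 11 and 8 of them passed. Their camera adjusted p was 9.17e-11, 2.29e-09 and 8.23e-05, with adjusted p = 0.0621, 0.0499 and 0.174 with an estimated correlation. The antigen-presentation gene H2-DMb1 rose by 5.97 ± 0.22, the apolipoprotein gene Apoe by 3.44 ± 0.17 and the antiviral gene Bst2 by 5.07 ± 0.24. Of the inflammatory cytokine and chemokine list, 6 of 7 measured members were higher, 0 were lower and 1 did not pass (6 passed when adjusted over the list alone). That list had a median of 3.54 (camera adjusted p = 5.09e-04, adjusted p = 0.163 with an estimated correlation), and Icam1, a leukocyte adhesion molecule gene, lay at 4.75 ± 0.31.

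Neuronal and astrocytic genes lay on the IgG side of this comparison. Among neuronal genes, 0 of 22 measured members were higher, 20 were lower and 2 did not pass. The neuronal median was -2.67 (camera adjusted p = 3.18e-08, adjusted p = 0.177 with an estimated correlation), and 20 passed when adjusted over the list alone. The glutamate receptor subunit gene Grin2b lay at -3.08 ± 0.23 and Gad1, which encodes an enzyme of GABA synthesis, at -3.22 ± 0.26. Among astrocyte genes, 0 of 20 measured members were higher, 17 were lower and 3 did not pass. The astrocyte median was -1.35 (camera adjusted p = 4.51e-04, adjusted p = 0.259 with an estimated correlation), and 18 passed when adjusted over the list alone. Aldoc lay at -2.22 ± 0.19 and the glutamate transporter gene Slc1a2 at -1.62 ± 0.20. Of the cytosolic ribosomal protein genes, 52 of 71 measured members were higher, 2 were lower and 17 did not pass. Their median was 1.16 (camera adjusted p = 7.15e-06, adjusted p = 0.177 with an estimated correlation), and 54 passed when adjusted over the list alone. Adjustment for transcript GC content and length with the replicate block ended this call (median 0.13, adjusted p = 0.353) and that of Slc1a2 (-0.10, adjusted p = 0.675). Over all genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6465 of 10021, with 2862 higher and 3603 lower. Above the expression minimum, the largest increases were those of Ticam2, a Toll-like receptor adaptor gene (7.59 ± 0.49, adjusted p = 2.14e-09), and the leukocyte lysosomal gene Laptm5 (7.57 ± 0.27, adjusted p = 5.07e-12). Among the large decreases was that of the GABA receptor subunit gene Gabrb2 (-5.51 ± 1.06). Pcdh7 had no count in any HA library and was at least 27.1-fold lower against a floor of 3 counts over the group. Without TMM scaling the median of all genes moved from -0.28 to -0.70 and the split to 2102 higher and 4749 lower. With all 8 groups in one fit the split was 2464 to 5746. Fold changes fell with transcript length across genes (Spearman's rho = -0.366). With the adjustment for GC content and length with the replicate block, 5188 of the 6465 calls kept their direction and 50 were called in the opposite one.

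In the Sall1 line the same comparison recovered both microglial and glial transcripts. Of the homeostatic microglia list, 22 of 25 measured members were higher, 3 were lower and 0 did not pass. The microglial median was 1.85 (camera adjusted p = 1.12e-11, adjusted p = 0.0893 with an estimated correlation), and 25 passed when adjusted over the list alone. C1qa rose by 3.59 ± 0.16, the lipid receptor gene Trem2 by 3.51 ± 0.16 and Aif1 by 3.48 ± 0.17. P2ry12, a purinergic receptor gene of microglia, was lower (-2.65 ± 0.35, adjusted p = 3.53e-06). Astrocyte genes were higher in the same libraries, where 16 of 20 measured members were higher, 1 was lower and 3 did not pass. Their median was 2.01 (camera adjusted p = 5.06e-09, adjusted p = 0.0893 with an estimated correlation), and 18 passed when adjusted over the list alone. Mlc1 rose by 3.48 ± 0.16, the neurotensin receptor gene Ntsr2 by 2.91 ± 0.17 and the growth factor receptor gene Fgfr3 by 2.66 ± 0.16. Of the oligodendrocyte list, 13 of 16 measured members were higher, 3 were lower and 0 did not pass, and of its precursor list 8 of 11 measured members were higher, 0 were lower and 3 did not pass. The oligodendrocyte median was 1.77 (camera adjusted p = 5.99e-06, adjusted p = 0.111 with an estimated correlation), and that of precursors 2.03 (camera adjusted p = 1.21e-04, adjusted p = 0.122 with an estimated correlation). When adjusted over the list alone, 16 and 8 passed. The myelin gene Mog rose by 3.50 ± 0.17, and the lineage transcription factor genes Olig1 and Olig2 by 3.24 ± 0.18 and 3.08 ± 0.20. All 10 measured ependymal genes were higher, for example Rarres2 (3.01 ± 0.31), with a median of 2.27 (camera adjusted p = 0.00327, adjusted p = 0.232 with an estimated correlation). Fibroblast and leptomeningeal genes were higher in 5 of 6 cases, with a median of 1.68 (camera adjusted p = 0.0231, adjusted p = 0.219 with an estimated correlation). The fibroblast call ended without any 1 of HA replicates 7, 9, 17 and 21 and IgG replicate 9 (adjusted p from 0.0537 to 0.131), where the median fell to between 0.88 and 1.12. It also ended without the low-count filter (median 0.68, adjusted p = 0.0928). Choroid plexus genes went both ways (2 higher, 2 lower of 7) and did not pass, with adjusted p = 0.767, a median of 0.05 and a mean of -0.02. Ttr, the gene of a thyroid hormone carrier, was higher by 2.00 ± 0.21.

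Neuronal and endothelial genes were depleted from Sall1 HA. For neurons, 0 of 22 measured members were higher, 21 were lower and 1 did not pass, with the kinase gene Camk2a at -3.63 ± 0.21. The neuronal median was -2.32 (camera adjusted p = 1.69e-09, adjusted p = 0.0893 with an estimated correlation), and 22 passed when adjusted over the list alone. All 12 measured endothelial genes were lower, among them the VEGF receptor gene Flt1 (-4.49 ± 0.27). The endothelial median was -4.52 (camera adjusted p = 7.20e-07, adjusted p = 0.202 with an estimated correlation). Of perivascular and border macrophage genes 3 could be tested, 1 was higher and 1 lower. That list did not pass (camera adjusted p = 0.992), with a median of -0.05 and a test direction of up. MHC class II genes split as well, with 2 higher and 3 lower (adjusted p = 0.987, median -0.79, test direction up). Nuclear-encoded respiratory chain genes were higher in 60 of 75 cases, with Uqcr10 at 3.18 ± 0.16 and a median of 1.27 (camera adjusted p = 2.20e-11, adjusted p = 0.122 with an estimated correlation). This call ended with adjustment for GC content and length with the replicate block (median 0.11, adjusted p = 0.738). Adjusted over the list alone, 10, 5, 4, 12, 2, 5 and 66 ependymal, fibroblast, choroid plexus, endothelial, macrophage, MHC class II and respiratory chain genes passed. The test called 8230 of 11545 genes, 4064 higher and 4166 lower. Without TMM scaling the split became 2869 to 5427, and the median of all genes moved from -0.03 to -0.44. The adjustment for GC content and length with the replicate block kept 5808 of the 8230 calls in their direction and turned 279 to the opposite one. Above the expression minimum, the largest increases were those of Mt2, a metallothionein gene (4.72 ± 0.17, adjusted p = 5.19e-12), Hotairm1 (4.71 ± 0.41) and the calcium-binding protein gene S100a4 (4.65 ± 0.27). The largest decrease was that of Hecw1, a ubiquitin ligase gene (-8.51 ± 0.75). Fold changes fell with transcript length across genes (Spearman's rho = -0.526). These extremes follow that trend, with lengths of 551 (Mt2), 251 (Hotairm1), 494 (S100a4) and 9429 bases (Hecw1).

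Whether enrichment over IgG differed between the lines was tested as an interaction over the 16 homogenate libraries. All 25 measured microglial genes had lower enrichment in the Sall1 line, with a median of -3.38 (camera adjusted p = 7.36e-52, adjusted p = 3.22e-04 with an estimated correlation). The growth factor receptor gene Csf1r lay at -3.85 ± 0.25 and C1qa at -3.63 ± 0.24. Perivascular and border macrophage genes were lower in 11 of 13 cases, with a median of -4.93 (camera adjusted p = 5.51e-11, adjusted p = 0.00120 with an estimated correlation). Pf4 lay at -6.86 ± 0.54 and Stab1 at -4.63 ± 0.30. All 6 MHC class II genes were lower, with Cd74, the invariant chain gene, at -6.30 ± 0.44 and a median of -5.54 (camera adjusted p = 1.61e-18, adjusted p = 3.22e-04 with an estimated correlation). In the other direction stood all 20 astrocyte genes, with a median of 3.28 (camera adjusted p = 1.28e-31, adjusted p = 3.22e-04 with an estimated correlation). Oligodendrocyte genes were more enriched in the Sall1 line in 12 of 16 cases and precursor genes in 9 of 12. Their medians were 3.03 (camera adjusted p = 5.07e-15, adjusted p = 3.22e-04 with an estimated correlation) and 2.94 (camera adjusted p = 2.02e-07, adjusted p = 0.00103 with an estimated correlation). Respiratory chain genes were more enriched in 55 of 75 cases and less in 1, with a median of 1.06 (camera adjusted p = 3.28e-11, adjusted p = 0.0193 with an estimated correlation). Enrichment of neuronal genes differed in 4 cases upward and 2 downward among 22. The neuronal list did not pass (camera adjusted p = 0.729, median -0.04, test direction up). When adjusted over the list alone, 25, 11, 6, 20, 12, 9, 62 and 4 microglial, macrophage, MHC class II, astrocyte, oligodendrocyte, precursor, respiratory chain and neuronal genes passed. edgeR called 3965 of 12308 genes, 2277 higher and 1688 lower. The split was 1951 to 1957 with DESeq2, 2051 to 1842 with median-ratio size factors and 3209 to 1427 with all 8 groups in one fit (medians of all genes -0.30, 0.06 and 0.38, from 0.15).

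A direct test of Sall1 HA against Cx3cr1 HA set the contents of both precipitates side by side. Every measured microglial gene was lower in Sall1 HA (25 of 25), with a median of -3.80 (camera adjusted p = 5.65e-43, adjusted p = 9.08e-04 with an estimated correlation). Csf1r lay at -4.61 ± 0.18 and the integrin gene Itgam at -4.26 ± 0.18. Macrophage genes were lower in 10 of 11 cases, with a median of -5.28 (camera adjusted p = 1.01e-11, adjusted p = 0.0141 with an estimated correlation), and the MHC class II genes H2-Eb1 and Cd74 lay at -6.87 ± 0.32 and -6.47 ± 0.27. Astrocyte genes were higher in all 20 cases, with a median of 3.07 (camera adjusted p = 1.36e-20, adjusted p = 0.0117 with an estimated correlation) and the clusterin gene Clu at 3.85 ± 0.18. Genes of mural cells, the pericytes and smooth muscle of vessels, were higher in all 5 measured cases, with Vtn at 3.34 ± 0.25 and a median of 3.35 (camera adjusted p = 0.00775, adjusted p = 0.207 with an estimated correlation). Of the immediate early genes, which respond within minutes to stimulation, 5 were higher and 6 lower of 18 (camera adjusted p = 0.634). Adjusted over the list alone, 25, 11, 20, 5 and 11 microglial, macrophage, astrocyte, mural cell and immediate early genes passed. The test called 4808 of 9092 genes, 2471 higher and 2337 lower. With all 8 groups in one fit the split was 3847 to 1897. Without TMM scaling it was 3051 to 1932, and the median of all genes moved from 0.05 to 0.24. Cmbl and Inmt had no count in any Cx3cr1 HA library and were at least 23.6-fold and 14.8-fold higher in Sall1 HA. Across 9837 genes, which are not independent replicates, the HA against IgG fold changes of the lines had Pearson's r = 0.667 and Spearman's rho = 0.678. Of these genes 1963 were higher in both (968 for independent lists), 2483 lower in both (1279) and 564 opposite.

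Direct precipitation was compared with precipitation after sorting to see what cell isolation changes in the recovered RNA. In the Cx3cr1 line the immediate early genes were lower in HA than in titled SortIP, as 1 of 23 measured members was higher, 21 were lower and 1 did not pass. Their median was -3.44 (camera adjusted p = 5.94e-07, adjusted p = 0.352 with an estimated correlation), and 23 passed when adjusted over the list alone. The AP-1 subunit gene Jun lay at -5.49 ± 0.38 and Zfp36, the gene of an mRNA decay factor, at -5.93 ± 0.43. Nr4a1, a nuclear receptor gene, was instead higher (1.69 ± 0.52, adjusted p = 0.0151), although its groups overlapped. The Nr4a1 call ended without HA replicate 1 (1.64, adjusted p = 0.0603) and with adjustment for GC content and length with the replicate block (0.81, adjusted p = 0.127). Of the cytokine and chemokine genes, 0 of 12 measured members were higher, 11 were lower and 1 did not pass. They had a median of -2.72 (camera adjusted p = 0.00147, adjusted p = 0.352 with an estimated correlation), with the interleukin gene Il1a at -5.97 ± 0.66 and Cd14, an endotoxin co-receptor gene, at -1.94 ± 0.20. Tnf, the tumour necrosis factor gene, and Casp1, the inflammasome protease gene, had no count in any HA library and were at least 32.1-fold and 26.6-fold lower. Perivascular and border macrophage genes were higher in HA, as 5 of 7 measured members were higher, 0 were lower and 2 did not pass. Their median was 4.76 (camera adjusted p = 7.89e-05, adjusted p = 0.142 with an estimated correlation), with Pf4 at 5.40 ± 0.27 and the transglutaminase gene F13a1 at 5.39 ± 0.48. Neuronal genes were higher in all 18 measured cases, with a median of 3.98 (camera adjusted p = 4.18e-12, adjusted p = 0.148 with an estimated correlation) and the neuronal surface gene Thy1 at 5.27 ± 0.25. Astrocyte genes were higher in 11 of 13 cases, with a median of 4.24 (camera adjusted p = 3.86e-08, adjusted p = 0.142 with an estimated correlation) and Clu at 3.72 ± 0.21. Neuronal genes took 0.4455% of counts in Cx3cr1 HA against 1.84% in Cx3cr1 IgG, and astrocyte genes 0.195% against 0.765%. For both lists, RNA bound without the tag therefore cannot be told apart from RNA that sorting removes. Microglial genes went both ways, as 7 of 26 measured members were higher, 11 were lower and 8 did not pass. P2ry12 (38.6% GC) lay at -4.74 ± 0.25 and C1qa (59.5% GC) at 1.68 ± 0.16. With adjustment for GC content and length with the replicate block the C1qa call ended (0.04, adjusted p = 0.814). Under that adjustment 2 microglial genes were higher and 16 lower, so the split in direction follows GC content or length in part. The microglia list did not pass (median -0.22, camera adjusted p = 0.0695). It passed as lower by description (median -0.67, camera adjusted p = 0.00113, adjusted p = 0.169 with an estimated correlation) and in other settings given in the closing section. By description the medians of immediate early, cytokine, macrophage, neuronal and astrocyte genes were -3.09, -2.44, 4.47, 3.02 and 3.59, with a largest camera adjusted p of 6.25e-04 and a smallest adjusted p of 0.161 with an estimated correlation. When adjusted over the list alone, 11, 5, 18, 13 and 19 cytokine, macrophage, neuronal, astrocyte and microglial genes passed. The test called 5743 of 8198 genes by title (2671 higher, 3072 lower) and 5250 by description. By title the split was 2213 to 3585 without TMM scaling (median of all genes -0.36 instead of -0.12) and 3729 to 3790 with DESeq2.

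In the Sall1 line, where the labels do not conflict, immediate early genes were also lower in HA than in SortIP, as 1 of 23 measured members was higher, 17 were lower and 5 did not pass. Their median was -2.89 (camera adjusted p = 0.00834, adjusted p = 0.528 with an estimated correlation), with the transcription factor gene Klf6 at -3.99 ± 0.22 and Nr4a1 higher at 3.58 ± 0.25. Cytokine and chemokine genes were lower in 12 of 13 cases, with the chemokine gene Ccl2 at -8.61 ± 0.49. Their median was -5.82 (camera adjusted p = 8.12e-06, adjusted p = 0.199 with an estimated correlation), or -5.65 with genes at 0 set to their bounds. All 26 microglial genes were lower, with a median of -4.0 (camera adjusted p = 8.92e-24, adjusted p = 0.0152 with an estimated correlation). Among them were the receptor genes Gpr34 (-10.02 ± 0.33) and P2ry12 (-8.49 ± 0.27), whose transcripts have the lowest GC content of the list (37.1% and 38.6%). Homeostatic microglia genes took 0.736% of counts in Sall1 HA and 10.9% in Sall1 SortIP. Lower immediate early and cytokine RNA in Sall1 HA therefore cannot be told apart from a smaller share of microglial RNA, and shows no effect of cell isolation by itself. Cd48, a leukocyte surface gene, had no count in HA and was at least 663-fold lower. Astrocyte genes were higher in 19 of 20 cases, with Mlc1 at 8.24 ± 0.26 and a median of 6.13 (camera adjusted p = 2.92e-11, adjusted p = 0.188 with an estimated correlation). Oligodendrocyte genes were higher in 13 of 14 cases, with Mog at 9.28 ± 0.37 and a median of 6.04 (camera adjusted p = 5.46e-09, adjusted p = 0.188 with an estimated correlation). Precursor genes were higher in 9 of 10 cases. Their median was 7.50 (camera adjusted p = 1.42e-04, adjusted p = 0.199 with an estimated correlation), or 5.70 with bounds. Adjusted over the list alone, 18, 13, 26, 19, 14 and 10 immediate early, cytokine, microglial, astrocyte, oligodendrocyte and precursor genes passed. Fmod, which encodes the matrix protein fibromodulin, and Olig2 had no count in SortIP and were at least 147-fold and 119-fold higher. edgeR called 8412 of 10494 genes, 4448 higher and 3964 lower. The majority turned without TMM scaling, with 4209 higher and 4260 lower (median of all genes -0.03 instead of 0.12), while DESeq2 gave 5659 to 4261. Fold changes of HA against SortIP rose with the GC content of the transcript. Genes in the lowest of 5 GC groups had a median of -1.37 and those in the highest 1.03 in the Sall1 line, against -1.85 and 0.80 in the Cx3cr1 line. With adjustment for GC content and length with the replicate block, 3759 of the 5743 Cx3cr1 calls kept their direction and 237 were called in the opposite one. Of the 8412 Sall1 calls, 6992 kept their direction and 183 were opposite.

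Precipitation of sorted microglia of the Sall1 line (SortIP against Sort) set ribosome-bound RNA against total RNA. Microglial transcripts were higher after precipitation, as 12 of 26 measured members were higher, 0 were lower and 14 did not pass. Their median was 0.33 (camera adjusted p = 2.13e-04, adjusted p = 0.0851 with an estimated correlation), and 14 passed when adjusted over the list alone. C1qa lay at 0.81 ± 0.10. Nuclear-retained RNAs were lower in 2 of 4 cases and higher in 0, with a median of -1.08 (camera adjusted p = 0.00436, adjusted p = 0.331 with an estimated correlation). The paraspeckle RNA Neat1 lay at -1.32 ± 0.26 and Kcnq1ot1 at -0.84 ± 0.24. The Kcnq1ot1 call ended without Sort replicate 17 or SortIP replicate 7, 9 or 21 (fold changes from -0.78 to -0.70, adjusted p from 0.0681 to 0.107). Its fold change was 0.03 with adjustment for GC content and length with the replicate block. Neuronal genes were higher in 5 of 12 cases, with a median of 1.32 (camera adjusted p = 4.43e-11, adjusted p = 0.202 with an estimated correlation). They were at low levels, with Gad1 at 23.6 ± 4.63 CPM in SortIP against 4.00 ± 3.65 CPM in Sort (2.58 ± 0.45, adjusted p = 0.00159). When adjusted over the list alone, 2 and 11 nuclear and neuronal members passed. Above the expression minimum, Gpm6a, a neuronal membrane glycoprotein gene, rose most (2.50 ± 0.43, adjusted p = 0.00204). Among the largest decreases were those of Zbed6 (-2.43 ± 0.44, adjusted p = 0.00233) and Nlrp1b, an inflammasome sensor gene (-2.25 ± 0.44, adjusted p = 0.00345). edgeR called 906 of 8603 genes (469 higher, 437 lower), and 393 without Sort replicate 17. Without TMM scaling the split became 219 to 800, with a shift of the median of all genes from 0.00 to -0.14.

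By titles, this comparison gave opposite signs in the Cx3cr1 line. Microglial genes were lower in titled SortIP, as 0 of 26 measured members were higher, 10 were lower and 16 did not pass. Their median was -0.23 (camera adjusted p = 4.74e-04, adjusted p = 0.247 with an estimated correlation), and 10 passed when adjusted over the list alone. C1qa lay at -0.75 ± 0.11, while Neat1 was higher (0.84 ± 0.19, adjusted p = 0.00719), as was Nlrp1b (3.21 ± 0.76, adjusted p = 0.0324). Respiratory chain genes were lower in 7 of 72 cases and higher in 1 (8 passed when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 8.00e-04, adjusted p = 0.762 with an estimated correlation). The Nlrp1b call ended without any 1 of titled Sort replicates 1 to 4 and titled SortIP replicate 4 (adjusted p from 0.0580 to 0.105), although its fold change stayed between 2.90 and 3.70. That of Neat1 ended with adjustment for GC content and length with the replicate block (0.46, adjusted p = 0.0801). With groups by description every sign is turned around by construction. edgeR called 1115 of 8704 genes, 554 higher and 561 lower by title. Without TMM scaling the split was 999 to 295, with the median of all genes at 0.13 instead of 0.01. The count fell to 456 and 645 without titled Sort replicates 1 and 3, and to 551 and 544 without titled SortIP replicates 1 and 4. Across 8381 genes, which are not independent replicates, the fold changes of the lines had r = -0.767 and rho = -0.749. They followed transcript GC content with opposite signs (Spearman's rho = -0.335 by title in the Cx3cr1 line and 0.318 in the Sall1 line). How much of the correlation this trend accounts for was not tested. Of the genes edgeR called in both, 489 had opposite signs and 0 the same sign, against 30.0 higher and 28.4 lower in both for independent lists. The interaction over the 16 sorted libraries by title called 2686 of 9212 genes, with C1qa at 1.57 ± 0.15 and Neat1 at -2.14 ± 0.35. Without TMM scaling its split of 1327 higher and 1359 lower became 785 to 2214 (median of all genes -0.01 and -0.28). By description edgeR called 0 genes and DESeq2 0, with 253 at an unadjusted p under 0.05 where chance gives 461. By description its neuronal list passed as higher, with a median of 0.56 (camera adjusted p = 1.33e-06, adjusted p = 0.504 with an estimated correlation), and its MHC class II list as lower, with a median of -1.29 (camera adjusted p = 3.98e-05, adjusted p = 0.331 with an estimated correlation).

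**Figure D2:**
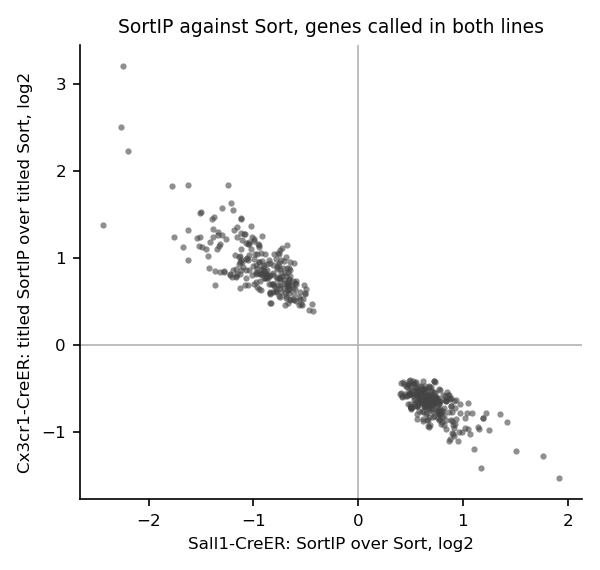
Log2 fold change of SortIP against Sort for each gene called in both lines, with the Sall1 line on the x axis and the Cx3cr1 line, grouped by title, on the y axis. All 489 points lie in the quadrants of opposite sign.

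Sorted microglia were compared between the lines in total RNA (Sort) and in ribosome-bound RNA (SortIP). Perivascular and border macrophage genes, of which 6 of 17 were measured in Sort and 3 in SortIP, were higher in the Sall1 line in both. All measured members were higher. Their medians were 2.02 (camera adjusted p = 5.01e-12, adjusted p = 0.0732 with an estimated correlation) in Sort and 2.93 (camera adjusted p = 3.83e-18, adjusted p = 0.00816 with an estimated correlation) in SortIP. Cp, which encodes ceruloplasmin, averaged 220.2 ± 15.8 CPM in Sall1 Sort and 7.51 ± 2.89 CPM in Cx3cr1 titled Sort. Its fold change was 4.71 ± 0.21 in Sort (adjusted p = 4.29e-14) and 4.68 ± 0.29 in SortIP, and that of the mannose receptor gene Mrc1 was 3.02 ± 0.37 and 2.93 ± 0.28. Cp and Mrc1 belong to the list and are among the 3 members measured in SortIP, so their values are part of its result. The chemokine receptor gene Ccr1 (4.51 ± 0.24 and 5.10 ± 0.30) and Cdkn1a, which encodes the cell cycle inhibitor p21 (3.45 ± 0.22 and 3.48 ± 0.30), were higher in both. Upk1b, a uroplakin gene, was lower (-3.45 ± 0.22 and -3.60 ± 0.29), as was Angptl7 (-3.21 ± 0.50 and -2.73 ± 0.58). The Angptl7 call in SortIP ended without Sall1 SortIP replicate 9 (-2.71, adjusted p = 0.0798) or 17 (-2.95, adjusted p = 0.05005), with about the same fold change. Of disease-associated microglia genes, 6 of 13 measured members were higher, 2 were lower and 5 did not pass in Sort, with a median of 0.26 (camera adjusted p = 6.52e-04, adjusted p = 0.267 with an estimated correlation). In SortIP 6 of 13 measured members were higher, 0 were lower and 7 did not pass, with a median of 0.58 (camera adjusted p = 5.14e-10, adjusted p = 0.0591 with an estimated correlation). By description 5 were higher and 0 lower in Sort, with a median of 0.43 (camera adjusted p = 1.30e-15, adjusted p = 0.0261 with an estimated correlation). In SortIP by description 4 were higher and 0 lower, with a median of 0.26 (camera adjusted p = 2.28e-13, adjusted p = 0.0450 with an estimated correlation). The lipoprotein lipase gene Lpl lay at 1.64 ± 0.22 in Sort and 2.05 ± 0.27 in SortIP, the oxidase subunit gene Cybb at 2.02 ± 0.21 and 2.44 ± 0.22, and Apoe at 2.83 ± 0.25 in SortIP. Adjusted over the list alone, 6 and 8 macrophage and disease-associated genes passed in Sort and 3 and 6 in SortIP. Sall1 itself was lower in the Sall1 line in Sort (-0.71 ± 0.13, adjusted p = 4.50e-04) and in SortIP (-0.77 ± 0.15, adjusted p = 0.00191). Cx3cr1 was higher in Sort (0.95 ± 0.12, adjusted p = 6.78e-06) and lay at 0.52 ± 0.21 in SortIP (adjusted p = 0.128). By description Cx3cr1 lay at 0.67 ± 0.24 in Sort (adjusted p = 0.341) and 0.79 ± 0.14 in SortIP (adjusted p = 5.36e-04). In mouse sums its call ended (0.70 ± 0.18, adjusted p = 0.0847). By title in SortIP it passed without the low-count filter (0.46, adjusted p = 0.0183) and without titled Cx3cr1 SortIP replicate 1 (0.68, adjusted p = 0.0466). Sall1 and Cx3cr1 are the loci that carry CreER in these lines, and an effect of CreER on their own RNA was not tested.

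The number of calls between sorted lines depended on the labels. By title edgeR called 2078 of 8688 genes in Sort (1035 higher, 1043 lower) and 919 of 8552 in SortIP (488 higher, 431 lower). By description it called 138 and 94. The macrophage list by description had 4 of 6 measured members higher in Sort (median 1.94, camera adjusted p = 7.65e-39) and 2 of 3 in SortIP (median 3.00, camera adjusted p = 2.20e-35). These had adjusted p = 0.00294 and 6.05e-04 with an estimated correlation. With the sorted libraries of each mouse summed, which needs neither label, 266 of 9966 genes were called. Among them were Cp (4.67 ± 0.23), Ccr1 (4.84 ± 0.18), Cdkn1a (3.36 ± 0.29), Mrc1 (2.99 ± 0.33), Upk1b (-3.58 ± 0.20) and Angptl7 (-2.92 ± 0.57), with a largest adjusted p of 0.0425. The macrophage list had 6 of 8 measured members higher in these sums (median 1.70, camera adjusted p = 2.70e-32, adjusted p = 0.0168 with an estimated correlation). Choroid plexus genes passed as higher too, as a list of 2 measured members of which 0 passed over all genes and 2 when adjusted over the list alone (median 1.11, camera adjusted p = 0.0118, adjusted p = 0.199 with an estimated correlation). Endothelial genes, of which 2 were measured, passed as lower (median -0.98, camera adjusted p = 0.00819, adjusted p = 0.118 with an estimated correlation). The homeostatic microglia list had 1 higher and 3 lower of 26 (adjusted p = 0.438). By title that list was instead lower in Sort, with a median of -0.46 (camera adjusted p = 6.52e-04, adjusted p = 0.236 with an estimated correlation), and higher in SortIP, with a median of 0.30 (camera adjusted p = 0.00198, adjusted p = 0.0591 with an estimated correlation). By description it did not pass in either (medians -0.05 and 0.06, adjusted p = 0.617 and 0.777). Without TMM scaling the splits by title were 1454 to 715 in Sort and 256 to 913 in SortIP, with medians of all genes of 0.12 and -0.17. The SortIP count fell to 469 and 501 without titled Cx3cr1 SortIP replicates 1 and 4, and to 487 and 560 without Sall1 SortIP replicates 17 and 7.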

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

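Chosen only after the data had been seen were the interaction over the sorted libraries and its splits, thinning to the shallowest library and the adjustment for GC content and length (the last 2 before their own results). Enrichment by HA over IgG differed between the lines in 3965 genes by the interaction test, and precipitation after sorting, by title, in 2686 genes. In Sall1 Sort replicate 21, which stood far from its group, the counts of the table made up 65.8% of the library total given with it, against 62.1 to 62.5% in the other 3. In Sall1 SortIP replicate 21 neutrophil genes took 0.0236% of counts, against 1.02e-04 to 0.00228% in the other 3. Choroid plexus genes took 0.404% in the same library, against 0.0669 to 0.122% in the other 3. Of 59 sets of 4 values examined for a far value 3 held one, where chance gives about 1 in 20. In each of the 11 comparisons 1 of 35 splits into 4 against 4 (of libraries, or of mice for the 2 interactions) called as many genes as the real split, which is that split itself, a share under 1 in 20. For the 5 comparisons between lines, which pair no libraries across the groups, 1 in 35 is the smallest share that the splits can give. Every other split of these mixes both lines within a group, which raises the spread, so few calls were bound to follow. The splits alone therefore do not exclude chance over 11 comparisons. Among the 5, those in Sort, in SortIP and in the difference in SortIP over Sort also rest on the titles. The highest count of another split was 0 in Cx3cr1 HA against IgG (6465 in the real split), 0 in Sall1 HA against IgG (8230), 0 in the difference in HA enrichment (3965) and 0 in Sall1 HA against Cx3cr1 HA (4808). It was 0 in Cx3cr1 HA against SortIP (5743), 0 in Sall1 HA against SortIP (8412) and 0 in the difference in SortIP over Sort (2686). For SortIP against Sort it was 31 in the Cx3cr1 line (1115) and 21 in the Sall1 line (906), and between lines 14 in Sort (2078) and 10 in SortIP (919). In the 6 comparisons within a line the libraries pair by mouse, and the 8 splits that part all 4 pairs are too few for a share under 1 in 20. Among these the highest count of another split was 0 in each of the 6. The other 27 splits, which keep some pairs together, hold the 31 and 21 calls named above.

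Titles and descriptions of the 8 sorted Cx3cr1 libraries give opposite assignments to Sort and SortIP, and the Sall1 line, whose labels do not conflict, served as a reference. The log2 ratio of titled SortIP over titled Sort correlated across 8603 genes with the Sall1 fold change at r = -0.697, -0.389, -0.492 and -0.559 in the 4 mice (mean -0.534, SD 0.129), whereas each Sall1 mouse correlated with the other 3 at a mean of 0.472 (SD 0.0635). Neat1, which stays in the nucleus, was lower after precipitation in the Sall1 line (-1.32 ± 0.26) and higher in titled SortIP of the Cx3cr1 line (0.84 ± 0.19). The latter call ended with adjustment for GC content and length with the replicate block (0.46, edgeR adjusted p = 0.0801). Fold changes also followed transcript GC content with opposite signs (Spearman's rho 0.318 in the Sall1 line, -0.335 by title in the Cx3cr1 line). A candidate explanation is therefore that the titles of the 2 groups are swapped, and by description the difference between lines fell to 0 genes by edgeR and 0 by DESeq2 (253 at an unadjusted p under 0.05), although camera called its neuronal (median 0.56, adjusted p = 1.33e-06) and MHC class II lists (median -1.29, adjusted p = 3.98e-05), with adjusted p = 0.504 and adjusted p = 0.331 with an estimated correlation. A true difference between the lines, in which precipitation acts on the same genes in opposite directions, predicts the same signs and was not tested directly. Precipitation alone would leave Sort alike between lines. By title, however, counts of the table made up 73.0% (SD 2.03) of the library total in Cx3cr1 Sort and 63.1% (SD 1.79) in Sall1 Sort. Between lines in Sort edgeR called 2078 genes by title, against 138 by description. These values argue against a difference in precipitation alone, and one that also reaches Sort stays open.

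Astrocyte and oligodendrocyte genes were higher in Sall1 HA than in IgG and than in Cx3cr1 HA, while neuronal genes were lower than in IgG. Transcripts bound without the tag would be no higher in HA than in IgG, but the astrocyte median over IgG was 2.01, and it was 1.48 after adjustment for GC content and length with the replicate block, so that neither accounts for it whole. Greater depth of the Sall1 HA libraries was also tested, and with all libraries thinned to the shallowest 17 of 20 astrocyte genes called higher than in Cx3cr1 HA (85%) were still called higher, which are all that could be tested. As a hypothesis, the tagged allele may have recombined in glia of the Sall1 line, where astrocyte genes took 2.09 ± 0.154% of counts in HA and Clu was at 4285 ± 565 CPM. The Percoll gradient and flow cytometry would remove such cells from sorted samples, where astrocyte genes took 0.114 ± 0.0108% (Sort) and 0.133 ± 0.0310% (SortIP), and no value here tests recombination itself.

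Perivascular and border macrophage genes, which were higher in Cx3cr1 HA than in titled SortIP, had a median of 5.23 over IgG, where transcripts bound without the tag would have 0 or less. Neuronal and astrocyte genes, higher in the same comparison, took 0.4455% and 0.195% of counts in Cx3cr1 HA. In Cx3cr1 IgG they took 1.84% and 0.765%, so RNA bound without the tag stays open as their source.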

How the results depend on the processing

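Chosen only after seeing the data were the interaction over the sorted libraries, thinning, groups by description together with the replicate block, and the adjustment for GC content and length. Apart from settings that leave out a library, the alternatives gave 838 values of named genes and 390 of named lists with the same direction and side of the threshold. They ended the call in 25 and 8 values, made one in 2 and 7, and turned the direction in 7 and 6. Without single libraries 12 gene values and 5 list values lost their call, 1 and 2 gained one, and 885 and 513 kept their side and direction. DESeq2, median-ratio size factors and the replicate block ended no call of a named gene or list that they tested. With the replicate block edgeR called 6720 genes in Cx3cr1 HA against IgG and 8280 in Sall1 HA against IgG, and with groups by title no count under the block was over 1.5 times from that without it. Depth limited the counts, and of the settings that kept the groups thinning left the fewest calls in each comparison. Thinned to the shallowest library, the counts of calls were 2125 for Cx3cr1 and 822 for Sall1 HA against IgG, 290 for the difference in HA enrichment, 1238 between HA precipitates, and 2290 for Cx3cr1 and 2470 for Sall1 HA against SortIP. They were 11 for Cx3cr1 and 34 for Sall1 SortIP against Sort, 97 and 43 between lines in Sort and SortIP, and 217 for the difference in SortIP over Sort. Thinning, which leaves fewer counts and tests fewer genes, ended calls of Olig2 in Sall1 HA against IgG (log2 fold change 1.99 against 3.08 unthinned), Stab1 in the difference in HA enrichment (-2.89 against -4.63), and Neat1 in Cx3cr1 (1.45 against 0.84) and Sall1 (-0.99 against -1.32) SortIP against Sort, as well as Kcnq1ot1 in the latter (-1.25 against -0.84). Between lines it ended calls of Sall1 (-0.21 against -0.71), Mrc1 (2.94 against 3.02) and Lpl (2.88 against 1.64) in Sort. In SortIP it ended those of Sall1 (-0.71 against -0.77), Mrc1 (2.15 against 2.93), Lpl (2.58 against 2.05) and Cybb (1.78 against 2.44). No direction turned among these, and the changes of Neat1 in the Cx3cr1 line, Kcnq1ot1 and Lpl were larger when thinned. Thinning also ended the list calls of cytokines in Cx3cr1 HA against IgG (median 2.96 against 3.54), fibroblasts in Sall1 HA against IgG (1.58 against 1.68) and neurons in Sall1 SortIP against Sort (0.82 against 1.32).

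A required fold of at least 2 was a cutoff on the estimated fold change of called genes, not a test of a 2-fold change. It left 184 calls in Cx3cr1 and 226 in Sall1 SortIP against Sort, 487 between lines in Sort, 321 in SortIP and 1781 in the difference in SortIP over Sort. With all 8 groups in one fit the counts of calls were 547 and 561 in SortIP against Sort of these lines and 1262 between lines in Sort, and Gpm6a, Zbed6 and Kcnq1ot1 did not pass in Sall1 SortIP against Sort (adjusted p from 0.0590 to 0.177). Their log2 fold changes there were about as large as in the separate fit, at 2.48, -2.48 and -0.89 against 2.50, -2.43 and -0.84. Without the low-count filter the lines differed in 1392 genes in SortIP, and the cause was not tested. By description the lines differed in 138 genes in Sort and 94 in SortIP, and their difference in SortIP over Sort held 0 genes by edgeR (253 at an unadjusted p under 0.05, 0 by DESeq2), or 3 with the replicate block. With the sorted libraries of each mouse summed, 266 genes differed in place of both counts between lines.

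By description, SortIP against Sort of the Cx3cr1 line reversed by construction, with C1qa at 0.75, Neat1 at -0.84, Nlrp1b at -3.21 and medians of 0.23 for microglia and 0.19 for the respiratory chain. With the replicate block as well these were 0.75, -0.83, -3.02, 0.23 and 0.18. Between lines in SortIP, the test direction of the microglia list turned around by description (median 0.0601) and in mouse sums (median -0.00773). Kcnq1ot1 in Sall1 SortIP against Sort moved to 0.0340 with adjustment for GC content and length with the replicate block. The causes of these were not tested except where by construction. Under the same adjustment 804 of 1115 calls in Cx3cr1 and 705 of 906 in Sall1 SortIP against Sort were kept in their direction, 3746 of 3965 in the difference in HA enrichment and 1978 of 2686 in the difference in SortIP over Sort. With the adjustment alone, 4454 of 4808 were kept between HA precipitates, 1581 of 2078 between lines in Sort and 640 of 919 in SortIP, and 0 were called in the opposite direction in these 7 comparisons. The microglia list passed as lower in Cx3cr1 HA against SortIP without TMM scaling (median -0.46), without the low-count filter, with all 8 groups in one fit, thinned, with the adjustment for GC content and length (-0.60) and without HA replicate 1 or titled SortIP replicate 1. Leaving out each library in turn gave between 456 and 1387 calls in Cx3cr1 and 393 and 785 in Sall1 SortIP against Sort, and between 469 and 1039 between lines in SortIP. In the other comparisons every count without a library lay within 1.5 times of that with all, from 5257 to 6519 in Cx3cr1 HA against IgG, for example.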

Other observations

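In this part the tests of distance to Cx3cr1 and Sall1, of macrophage markers and of dilution were chosen after the result was seen. With the sorted libraries of each mouse summed, 266 of 9966 genes differed between sorted microglia of the lines, 161 higher and 105 lower in the Sall1 line, and 34 did so by at least 4-fold (26 higher, 8 lower). Genes below that the report does not name were chosen after their values were seen. Higher in the Sall1 line were Adgrg5, an adhesion receptor gene (4.87 ± 0.27), Aoah, which encodes a hydrolase of bacterial lipopolysaccharide (3.48 ± 0.37), and Phlda3, a target gene of p53 like Cdkn1a (3.50 ± 0.43). The apolipoprotein genes Apoc1 (2.78 ± 0.38) and Apoe (2.30 ± 0.25) and the chemokine gene Ccl24 (2.57 ± 0.19) were higher as well. Lower were Pde2a, a phosphodiesterase gene (-2.58 ± 0.22), the lipase gene Liph (-2.20 ± 0.16), the RNA-binding protein gene Khdrbs3 (-2.38 ± 0.29) and Myo18b, a myosin gene (-2.90 ± 0.33). The largest adjusted p of these 10 was 0.00356. Of disease-associated microglia genes, 5 of 13 were higher in these sums and 0 lower (median 0.21, camera adjusted p = 1.06e-14, adjusted p = 0.0443 with an estimated correlation).

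Of these 4-fold genes 5 of 34 (14.7%, 95% interval 4.95 to 31.1) lie within 20 Mb of Cx3cr1 or Sall1. They are Adgrg5, Cacna1a and Cyp4f18 near Sall1 and Ccr1 and Lyzl4 near Cx3cr1. Sequence carried along with Cx3cr1 or Sall1 that acts only on genes this near is thus not the whole cause. An effect of such sequence on genes farther away cannot be seen by distance and was not tested. Distance to Rpl22, which is modified in both lines, was not tested. For those 5 such sequence is a candidate explanation, since 436 of 9930 other genes (4.39%) lie as near (1-sided Fisher p = 0.0160). Cx3cr1 and Sall1 themselves are left out of these other genes. More perivascular macrophages among sorted Sall1 cells would raise Mrc1 and 7 other markers of these cells alike, unless the flow cytometry gate, which the sources used here do not give, removed them. Mrc1 was higher by 3.14 ± 0.49 (107 against 13.1 CPM). The sum of the 7, of which Pf4 was most abundant (25.9 against 6.44 CPM), was higher by 1.88 ± 0.56. Their difference was -1.26 ± 0.74, or -2.49 ± 0.51 with Stab1, left out after a first result for its level of 356 CPM in sorted Cx3cr1 cells. These errors take both values as independent, although they come from the same mice, and the difference was not taken per mouse. It thus leaves macrophages open as a source. Dilution of microglia by other cells would lower the homeostatic microglia list along with the genes lower in the Sall1 line, but its median in these sums was -0.00773, and a difference of the lines in the state of their microglia was not tested.

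Choroid plexus genes took 0.242 ± 0.124% of counts in Sall1 Sort and 0.166 ± 0.161% in Sall1 SortIP (0.0862% without replicate 21), against 0.0377 ± 0.0163% in Cx3cr1 titled Sort and 0.129 ± 0.0594% in titled SortIP.

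Genes of blood leukocytes took small shares of counts in every group. The highest group means were 0.00230 ± 6.75e-04% for monocytes (Sall1 Sort), 0.00653 ± 0.0114% for neutrophils (Sall1 SortIP, 8.32e-04% without replicate 21, which held 0.0236%) and 0.00677 ± 0.00154% for lymphocytes (Cx3cr1 titled Sort).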
